A study of Mus musculus with 6 samples.

How the data were processed

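The data are RNA-seq gene counts of 6 libraries of GFP-positive Treg cells from mouse spleen, 3 from wild-type and 3 from BAF60b knockout mice. The deposited table holds raw read counts per Ensembl gene and library, as whole numbers without normalization. The submitters' processing notes name fastp 0.23.2, HISAT2 2.1.0, Picard, DESeq2 1.34.0 and the mm10 build. The order and role of these tools, the read counter, its strand setting, the annotation release and any removal of duplicates are not given in the sources used here. If the counting ignored strand, reads of overlapping genes on opposite strands cannot be told apart. The labels number the libraries within each genotype but do not say whether they came from separate mice, so p-values measure only the spread between these libraries. Sex-linked transcripts differed between the libraries of each genotype, so these are not repeat libraries of 1 RNA sample.

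The table lists 54232 genes, of which 24676 had at least 1 read. Spreadsheet software had turned 27 symbols into dates, and these were restored from the gene identifier. Coordinates are those of the table (mm10). Gene lengths, GC content and exon overlaps came from GENCODE mouse release M21 (Ensembl 96, the same build), which held 13588 of the 13602 tested genes, 12941 of them at the same start and end.

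Totals lay between 18167053 and 22502804 reads per library. A count of 0 allows up to 3 counts, which is between 0.133 and 0.165 CPM in a library, and such floors cover counting error only. Genes were kept by filterByExpr of edgeR (minimum count 10, minimum total 15), which left 13602. Counts were normalized by TMM, and genotype was tested with edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) without a block, at a Benjamini-Hochberg adjusted p under 0.05. The SE of a log2 fold change is its size divided by the square root of F. With 3 libraries against 3, an exact permutation test of 1 gene cannot go below p = 0.1. Before averaging, libraries were compared in pairs over genes with at least 20 counts: the chi-square per degree of freedom was at least 5.03 within a genotype, so no pair agreed within sampling noise.

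The test, the alternatives, the rule for naming genes and 29 gene lists were fixed before the data were examined. The lists cover Treg identity, chemoattractant receptors, adhesion and homing, motility, resting and effector Treg cells, SWI/SNF subunits, helper effector genes, T cell receptor and NF-kB targets, cell cycle, interferon response, glycolysis, oxidative phosphorylation, cholesterol synthesis, TGF-beta signalling, stress and dissociation, mitochondrial transcripts, ribosomal proteins, sex-linked genes and other cell types. The 27 lists with at least 3 tested members were tested by camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over the lists. The named genes are Smarcd2; the 12 largest rises and 12 largest falls among called genes with a mean of at least 2 CPM and no overlap between genotypes, without genes lacking an official name and receptor variable segments; from each list up to 4 called members by adjusted p, or the member with the smallest p where none was called; and Foxp3, Il2ra, Ctla4, Ikzf2, Ccr7, S1pr1, Itgae, Cxcr3, Ccr4, Smarcd1 and Smarcd3. Some genes that this rule names are not reported here. Any other gene is said to have been chosen after its values were seen. Called genes near Smarcd2 were counted with Fisher's exact test.

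The alternatives were RLE, upper-quartile and library-size normalization, no filter, a filter at a mean of 2 CPM, DESeq2 1.42.0, limma-voom with and without sample weights, robust dispersion, a fold of at least 2, an adjusted p under 0.1, a test against a fold of 1.2, the replicate number as a block, each library left out in turn, and removal of receptor segments, sex-linked genes and markers of other cells before normalization. List tests were repeated with an estimated correlation and with fry. A covariate for the share of male cells, a correction for GC content and exon length, and a fit without the libraries lacking Y chromosome transcripts were chosen after seeing the data.

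The steps were tested on simulated counts drawn from the means, dispersions and sizes of these libraries. In the simulated comparison of KO with WT over 13418 genes, edgeR called 22% of genes changed 1.25-fold, 56% of those changed 1.5-fold, 80% of those changed 2-fold and 96% of those changed 4-fold, with 9 false calls among 136. A simulated shift of -0.3 (log2) in 18 glycolysis genes was called. With no change simulated, 1 list and 0 genes were called by camera and edgeR. Genes were drawn independently of each other. The simulation therefore cannot show how camera with its preset correlation does on lists whose members move together. The correlation estimated in the data was 0.17 for glycolysis and 0.70 for the interferon response.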

Results

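Regulatory T cells (Treg cells), the CD4 T cells that hold immune responses in check, were isolated by their GFP signal from the spleens of wild-type (WT) mice and of mice with a conventional knockout (KO) of BAF60b, and their total RNA was sequenced. BAF60b is a subunit of the SWI/SNF (BAF) chromatin remodelling complex and is encoded by Smarcd2. The series holds 6 libraries, 3 of each genotype, and 1 comparison, KO against WT. The title of the series ties BAF60b to Treg cell migration, so receptors and adhesion molecules that guide migration were examined as groups of their own. Total counts were 18167053, 21038091 and 20125951 reads in WT 1, 2 and 3, and 20127159, 19365472 and 22502804 reads in KO 1, 2 and 3. Between 19459 and 20424 genes had at least 1 read in a library. Values below are read counts scaled to library size (CPM) after TMM normalization, given as mean ± SD with n = 3 per genotype. Log2 fold changes are KO minus WT, and adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 13602 genes.

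The targeted gene was measured first. Smarcd2 (ENSMUSG00000078619, chromosome 11, 106263179 to 106272972, minus strand, mm10) had 3729, 4173 and 3807 reads in the WT libraries and 1157, 1131 and 1335 reads in the KO libraries. Its level was 198.5 ± 6.25 CPM in WT and 58.2 ± 0.75 CPM in KO, a log2 fold change of -1.77 (SE 0.05, adjusted p = 6.77e-08), and it was lower in each KO library than in every WT library. Reads remained in KO at 0.293 times the WT level. Which exons the knockout removes is not given in the sources used here, so these reads may lie in parts of the transcript that the allele keeps. The paralogs encoding BAF60a and BAF60c did not pass the test: Smarcd1 had a log2 fold change of -0.01 (adjusted p = 0.940) and Smarcd3, at 1.83 CPM in WT, one of 0.07 (adjusted p = 0.925). Exons of Smarcd3 overlap those of Chpf2 on the opposite strand, so its count is uncertain. Of 25 other SWI/SNF subunits tested, 0 passed the edgeR threshold, over all genes or adjusted over the list alone, and 0 passed in DESeq2 or limma-voom, while 3 had an unadjusted p under 0.05 (camera adjusted p = 0.729). The smallest p among them was that of Smarcb1, with a log2 fold change of -0.19 and an adjusted p of 0.0559. That p was 0.0449 without KO replicate 1 and up to 0.178 with another library left out.

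**Figure D1:**
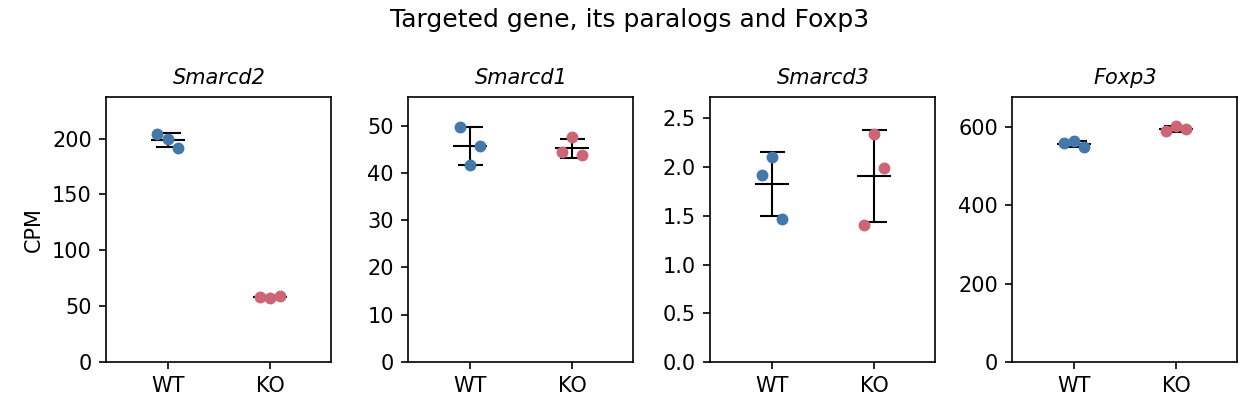
CPM of Smarcd2, its paralogs Smarcd1 and Smarcd3, and Foxp3 in each library (points) of WT (blue) and KO (red), with the mean (long bar) and SD (error bars, n = 3). Smarcd2 fell from 198.5 to 58.2 CPM, and the other 3 genes did not pass the test.

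Loss of BAF60b was accompanied by changes in 877 genes, 442 higher and 435 lower in KO, most of them small: the median absolute log2 fold change of these genes was 0.49, and 201 changed at least 2-fold, 130 upward and 71 downward. Among the 12 largest rises that the naming rule gave (mean of at least 2 CPM), the gene with the highest level was Gzmb, which encodes the cytotoxic protease granzyme B. It rose from 23.8 ± 1.69 to 92.2 ± 13.6 CPM (log2 fold change 1.95, SE 0.10, adjusted p = 3.24e-05). Gcnt1, an enzyme that builds core 2 O-glycans on selectin ligands, rose from 7.23 ± 3.26 to 27.5 ± 7.64 CPM (log2 fold change 1.93, SE 0.29, adjusted p = 0.00463). Zbtb32, a transcriptional repressor, rose by 1.71 on the log2 scale (SE 0.13, adjusted p = 0.000219). Ermn (log2 fold change 4.38), Cntnap1 (2.53), Dscam (2.08) and Srgap3 (1.95) rose from low levels, all at or under 4.51 CPM in WT. Exons of Cntnap1 overlap those of Plekhh3 on the opposite strand, which rose too (log2 fold change 1.67, adjusted p = 0.0185), so the count of Cntnap1 is uncertain. The other genes among the 12 largest rises were Capn11, Msrb3, Spire1, Zfp820 and Maged1, with log2 fold changes between 1.70 and 3.09. The call of Capn11 was lost in DESeq2 (adjusted p = 0.215), in limma-voom (adjusted p = 0.0732) and without WT replicate 2 (adjusted p = 0.0923). That of Zfp820 was lost in limma-voom (adjusted p = 0.0654) and when any 1 of the WT libraries or KO replicate 2 was left out (highest adjusted p = 0.107).

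Under the same rule, with a mean of at least 2 CPM, the largest falls besides Smarcd2 were those of Dsp (desmoplakin, log2 fold change -2.01), Asb2, a subunit of a ubiquitin ligase (-1.88), F13a1 (coagulation factor XIII A chain, -1.88), Lilr4b (-1.77), Nid2 (-1.77), Fcmr, the receptor for IgM (-1.67), Angptl2 (-1.52), Coro2b (-1.46), Ccr9 (-1.44), Apobr (-1.38) and Gpm6b (-1.33). Asb2 fell from 25.0 ± 2.68 to 6.84 ± 1.87 CPM (SE of the log2 fold change 0.17, adjusted p = 0.000337) and Angptl2 from 39.3 ± 4.69 to 13.7 ± 5.89 CPM (SE 0.23, adjusted p = 0.00521). Lilr4b has close paralogs. On the opposite strand, exons of Apobr overlap those of Cln3, and exons of Nid2 overlap those of Rtraf, which has many more reads. The counts of Lilr4b, Apobr and Nid2 are therefore uncertain. All 877 genes had no overlap between the 3 KO and the 3 WT values. Among all genes tested 25.7% had none, where chance gives 10%. Without WT replicate 1 or WT replicate 2 the count of changed genes was 344 in either case, and without WT replicate 3 it was 556.

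**Figure D2:**
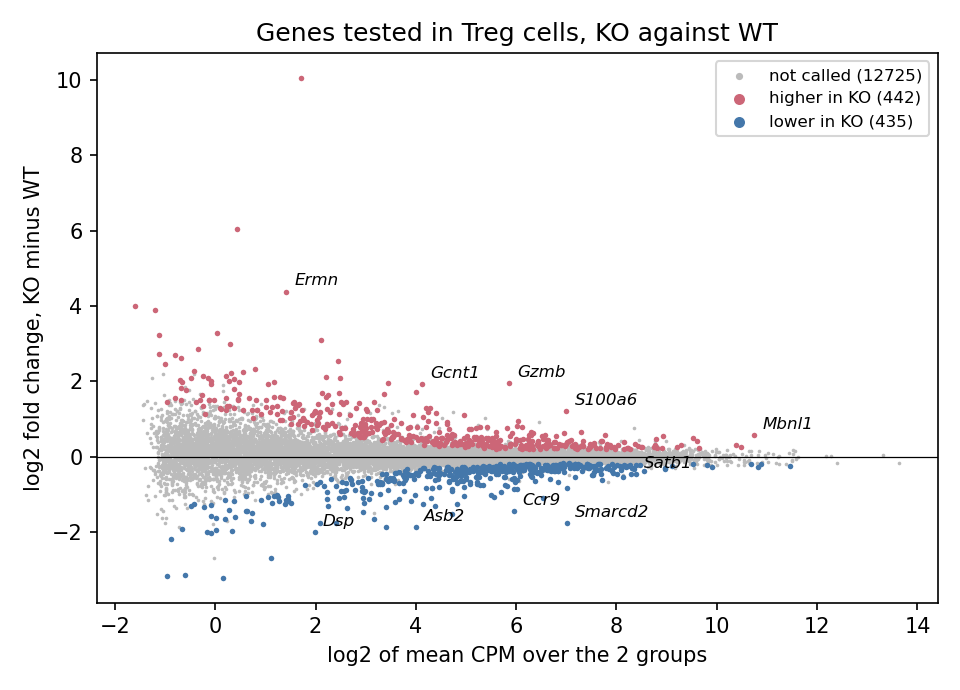
Log2 fold change (KO minus WT) of each gene tested against the log2 of its mean CPM, with genes higher in KO in red, lower in blue and not called in grey. The 442 rises and 435 falls are spread over the range of expression, with the largest fold changes among genes of low expression.

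Receptors that guide migration changed in both directions. Of 27 chemoattractant receptors tested, 5 rose and 2 fell, and 12 passed when adjusted over the list alone (8 higher, 4 lower). Ccr6, the receptor for CCL20, rose from 44.8 ± 1.75 to 86.6 ± 10.99 CPM (log2 fold change 0.95, SE 0.08, adjusted p = 0.000324). Ccr8, found on activated Treg cells, rose from 47.6 ± 3.19 to 69.9 ± 7.51 CPM (log2 fold change 0.56, SE 0.08, adjusted p = 0.00475). Ccr10 rose from 2.62 ± 0.75 to 8.46 ± 2.25 CPM (log2 fold change 1.69, adjusted p = 0.00475), but it lies inside the span of Cntnap1 (chromosome 11, 101170523 to 101190724), which rose too and is on the opposite strand. Annotated exons of Ccr10 do not overlap those of Cntnap1, so only reads from outside the Cntnap1 exons could be shared. The strand setting of the counting is not given in the sources used here, so the count of Ccr10 is uncertain. Ccr9, the gut-homing receptor for CCL25, fell from 90.6 ± 26.1 to 33.4 ± 13.1 CPM (log2 fold change -1.44, SE 0.27, adjusted p = 0.0114). Ccr9 is also in the list of dendritic cell markers, being expressed by plasmacytoid dendritic cells. Its call was lost without WT replicate 1 or WT replicate 2 (highest adjusted p = 0.0643). Ccr7, S1pr1, Cxcr3 and Ccr4 did not pass in edgeR: Ccr7 had a log2 fold change of -0.09 (adjusted p = 0.647), S1pr1 of 0.21 (adjusted p = 0.0945), Cxcr3 of 0.09 (adjusted p = 0.568) and Ccr4 of 0.22 (adjusted p = 0.130). Ccr4 passed without KO replicate 3 (adjusted p = 0.0129, and up to 0.323 with another library left out). S1pr1 passed in DESeq2 (adjusted p = 0.0245). With the male share of each library as a covariate, an alternative chosen after seeing the data, both passed as higher in KO (adjusted p = 0.0181 for S1pr1 and 0.00631 for Ccr4). By camera, which compares a list with the other genes, the list of receptors as a whole did not pass (adjusted p = 0.0972, and adjusted p = 0.897 with an estimated correlation). It passed, as higher in KO, without WT replicate 1 (adjusted p = 0.0456) or KO replicate 3 (adjusted p = 0.00161), and the adjusted p was up to 0.499 with another library left out. It passed also after removal of receptor segments, sex-linked genes and markers of other cells (adjusted p = 0.0150) and with the male share as a covariate (adjusted p = 0.00263). That removal took Ccr9, which fell in KO, out of the receptor list too, because Ccr9 is on the dendritic cell list.

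Adhesion and homing molecules were likewise divided, with 6 of 38 higher, 4 lower and 28 not called, and 15 past the threshold adjusted over the list alone. Cd44, the hyaluronan receptor, rose from 175.5 ± 6.51 to 259.8 ± 15.6 CPM (log2 fold change 0.57, SE 0.06, adjusted p = 0.000507). Icam1 (log2 fold change 0.35) and Itgae, the alpha chain of the E-cadherin-binding integrin CD103 (0.31, adjusted p = 0.0109), rose as well, while the sialyltransferase gene St3gal4 (-0.42) and Ly6c1 (-0.54) fell. Ly6c1 shares sequence with Ly6c2, so its count is uncertain. The camera test of this list gave an adjusted p of 0.729. Of 59 genes of the motility machinery, 2 rose and 2 fell, and 7 passed adjusted over the list alone. S100a6 rose from 77.1 ± 10.2 to 178.5 ± 17.9 CPM (log2 fold change 1.21, SE 0.10, adjusted p = 0.000252) and S100a10 by 0.47 on the log2 scale (adjusted p = 0.00415). Both encode small calcium-binding proteins. Arrb2, an arrestin that desensitises chemokine receptors, had a log2 fold change of -0.29 and Rgs10 of -0.21. Both calls were lost when any 1 of the WT libraries was left out, and that of Rgs10 also without KO replicate 2 or KO replicate 3 and after the GC and length correction (adjusted p = 0.0659), with highest adjusted p-values of 0.0817 and 0.152. The list as a whole had a camera adjusted p of 0.382.

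**Figure D3:**
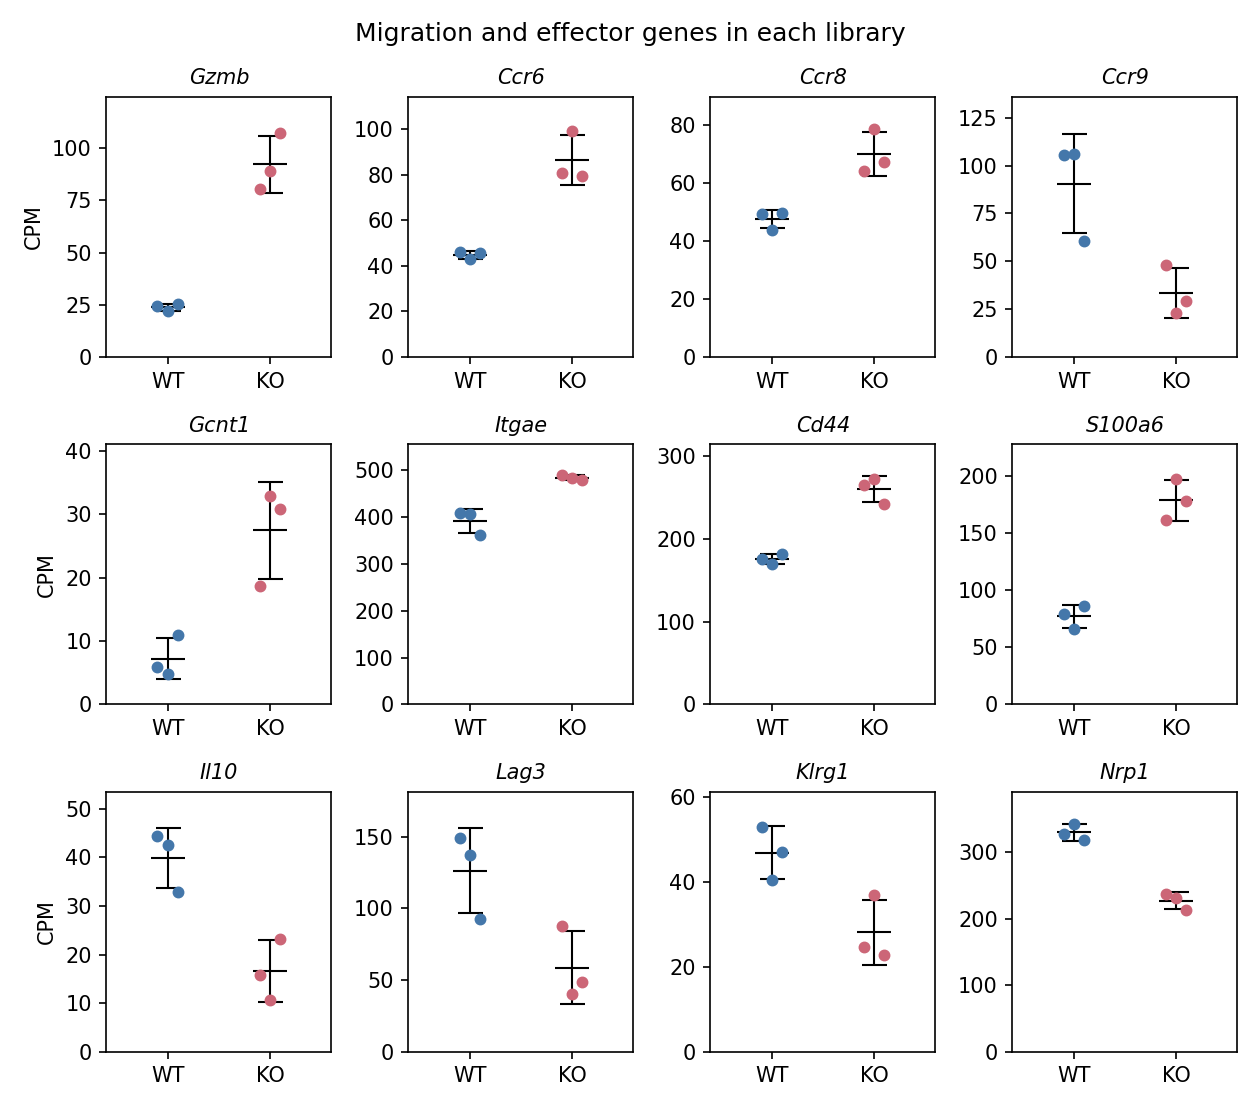
CPM in each library (points) of WT (blue) and KO (red) for migration and effector genes, with the mean (long bar) and SD (error bars, n = 3). Gzmb, Ccr6, Ccr8, Gcnt1, Itgae, Cd44 and S100a6 lie higher and Ccr9, Il10, Lag3, Klrg1 and Nrp1 lower in every KO library than in every WT library.

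Most Treg identity genes did not pass the test. Foxp3, the lineage-defining transcription factor, had 557.7 ± 7.37 CPM in WT and 595.8 ± 6.94 CPM in KO (log2 fold change 0.10, SE 0.04, adjusted p = 0.253), and neither Il2ra (log2 fold change -0.02, adjusted p = 0.834) nor Ctla4 (0.13, adjusted p = 0.468) passed. Of 25 identity and suppression genes, 6 rose, 2 fell and 17 were not called (10 passed adjusted over the list alone). Ikzf2, which encodes Helios, rose from 665.2 ± 37.4 to 888.3 ± 60.4 CPM (log2 fold change 0.42, SE 0.06, adjusted p = 0.00527), Plagl1 by 0.46 and Swap70 by 0.44. Nrp1, a surface marker of thymus-derived Treg cells, fell from 330.1 ± 12.3 to 227.4 ± 13.0 CPM (log2 fold change -0.54, SE 0.06, adjusted p = 0.000613). The camera test gave an adjusted p of 0.186. Camera looks for a shift of a list in 1 direction and can miss changes in both. Of all tested genes 6.45% were called, beside 8 of 25 identity genes, 18 of 37 effector Treg genes and 7 of 27 chemoattractant receptors. In other lists 0 of 25 SWI/SNF subunits, 0 of 42 oxidative phosphorylation genes and 4 of 59 motility genes were called. The mixed form of fry, which looks for change in either direction, gave adjusted p = 0.000691 for the identity list. It gave 0.000251 for effector Treg genes and 0.000678 for chemoattractant receptors. This form passed 18 of the 27 lists, so its result alone does not set these lists apart.

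Effector Treg genes changed in opposite directions. Of 37 tested, 11 rose and 7 fell (12 and 13 adjusted over the list alone). The camera adjusted p was 0.186, and it lay between 0.0467 (without KO replicate 3) and 0.956 with 1 library left out. Gzmb, Cd44, Ccr8 and Rora (log2 fold change 0.63, SE 0.08, adjusted p = 0.00266) rose. Falls in this list, named here after their values were seen, were those of the inhibitory cytokine gene Il10 (39.9 ± 6.13 to 16.6 ± 6.35 CPM, log2 fold change -1.26), the checkpoint receptor Lag3 (-1.10), Klrg1 (-0.74) and the IL-33 receptor gene Il1rl1 (-0.92). All 4 calls were lost without WT replicate 1 or WT replicate 2, that of Lag3 also without KO replicate 2 or KO replicate 3 and in DESeq2 (adjusted p = 0.0849), and that of Klrg1 also without WT replicate 3 or KO replicate 1, with highest adjusted p-values of 0.0590 for Il10, 0.146 for Lag3, 0.123 for Klrg1 and 0.0631 for Il1rl1. Among 21 genes of resting Treg cells 2 rose and 2 fell (6 adjusted over the list alone, camera adjusted p = 0.607). Id3 rose by 0.75 on the log2 scale (SE 0.08, adjusted p = 0.000539) and Satb1, a chromatin organiser, fell from 388.7 ± 5.88 to 281.0 ± 5.86 CPM (log2 fold change -0.47, adjusted p = 0.000391). Dapl1 had a log2 fold change of 0.79, and its call was lost without WT replicate 1, WT replicate 2, KO replicate 1 or KO replicate 2 (highest adjusted p = 0.179) and with the male share as a covariate (adjusted p = 0.0622).

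Cytokine and activation genes gave no common direction. Of 19 helper T cell effector genes 2 rose and 3 fell (9 adjusted over the list alone, camera adjusted p = 0.620): the interleukin 18 receptor gene Il18r1 rose by 0.82 on the log2 scale, and Tnfsf8 (-0.56) and Tnfsf11 (-0.58) were among the falls. Of 29 T cell receptor and NF-kB target genes, 4 rose and 4 fell (13 adjusted over the list alone, camera adjusted p = 0.584), with Tnfrsf9 (0.39) and Irf4 (0.28) higher and Birc3 (-0.26) lower. In the TGF-beta list 3 of 19 genes rose and 1 fell (5 adjusted over the list alone, camera adjusted p = 0.584). Tgfbr3 fell (log2 fold change -0.55, adjusted p = 0.00742). The log2 fold changes of Itgb8 (0.29) and Tgfbr1 (0.25) passed with all libraries, and both calls were lost when any 1 of the WT libraries was left out, that of Tgfbr1 also without KO replicate 1 or KO replicate 2 (highest adjusted p = 0.0963 and 0.139).

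By camera 5 lists stood apart from the other genes, 4 lower and 1 higher in KO, and 0 did so with an estimated correlation. Glycolysis genes were lower in KO, with a median log2 fold change of -0.21 over 18 genes, 5 of them called (11 adjusted over the list alone, camera adjusted p = 2.12e-06, and adjusted p = 0.603 with an estimated correlation). The wider glycolysis and gluconeogenesis pathway of the deposited annotation, looked at after the list results, did not pass, with 4 of 46 genes higher and 4 lower (camera adjusted p = 0.355 over 295 pathways). Its direction was that of the list (median log2 fold change -0.09, camera unadjusted p = 0.0490, and 0.347 with an estimated correlation). The glycolytic enzyme gene Eno1 fell from 307.1 ± 7.64 to 241.4 ± 17.8 CPM (log2 fold change -0.35, SE 0.06, adjusted p = 0.00834). Pfkfb3 had a log2 fold change of -0.31, Slc16a1 of -0.31 and the glucose transporter gene Slc2a1 of -0.27, and these 3 calls were lost without WT replicate 2 or WT replicate 3 (highest adjusted p = 0.0608, 0.0936 and 0.129). Those of Slc16a1 and Slc2a1 were also lost without KO replicate 1 or KO replicate 3, that of Slc16a1 without WT replicate 1 and that of Slc2a1 without KO replicate 2. Cell cycle genes were higher, with a median of 0.28 over 40 genes, 5 of them called (8 adjusted over the list alone, camera adjusted p = 9.53e-05, and adjusted p = 0.897 with an estimated correlation). The cell cycle pathway of the deposited annotation did not pass, with 9 of 115 genes higher and 2 lower (camera adjusted p = 0.310 over the same pathways). Its direction too was that of the list (median log2 fold change 0.03, camera unadjusted p = 0.0263, and 0.210 with an estimated correlation). Mki67 rose from 47.2 ± 5.42 to 72.9 ± 3.85 CPM (log2 fold change 0.63, SE 0.08, adjusted p = 0.00219) and Top2a by 0.53. Kif11 (log2 fold change 0.64) and Ccne1 (0.73) lost their calls without WT replicate 1 or KO replicate 1, and Kif11 also without WT replicate 2, WT replicate 3 or KO replicate 2 (highest adjusted p = 0.0833 and 0.0531). Interferon-stimulated genes were lower, with a median of -0.19 over 38 genes, 7 of them called (11 adjusted over the list alone, 10 lower, camera adjusted p = 9.53e-05, and adjusted p = 0.897 with an estimated correlation). Oas2 fell by 0.91 (adjusted p = 0.00871) and Isg20 by 0.42. Rsad2 (log2 fold change -0.83) and Ifit2 (-0.22) lost their calls without WT replicate 1 or WT replicate 2, and Ifit2 also without WT replicate 3 or KO replicate 2 (highest adjusted p = 0.0753 and 0.101). Ribosomal protein genes had a median of -0.15 over 40 genes, 3 of them called (15 adjusted over the list alone, camera adjusted p = 2.12e-06, and adjusted p = 0.897 with an estimated correlation). The called members Rpl7, Rps7 and Rpl37 had log2 fold changes of -0.20, -0.29 and -0.31, and each lost its call when any 1 of the WT libraries or KO replicate 3 was left out, Rpl7 also without KO replicate 1 and Rpl37 also without KO replicate 2 (highest adjusted p with a library left out 0.0968, 0.128 and 0.120). Rpl37 lost its call after the GC and length correction too (adjusted p = 0.0507). These families have many processed pseudogenes that can share their reads. Oxidative phosphorylation genes (0 of 42 called by edgeR, DESeq2 or limma-voom, 3 with an unadjusted p under 0.05, camera adjusted p = 0.669, smallest p that of Cyc1 with a log2 fold change of -0.12) and cholesterol synthesis genes (1 of 23, Nsdhl, log2 fold change -0.38, camera adjusted p = 0.584) did not stand apart. The cholesterol list passed, as lower in KO, without KO replicate 1 (adjusted p = 0.0449, and up to 0.989 with another library left out). The call of Nsdhl was lost when any 1 of the WT libraries or KO replicate 1 was left out (highest adjusted p = 0.0844).

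**Figure D4:**
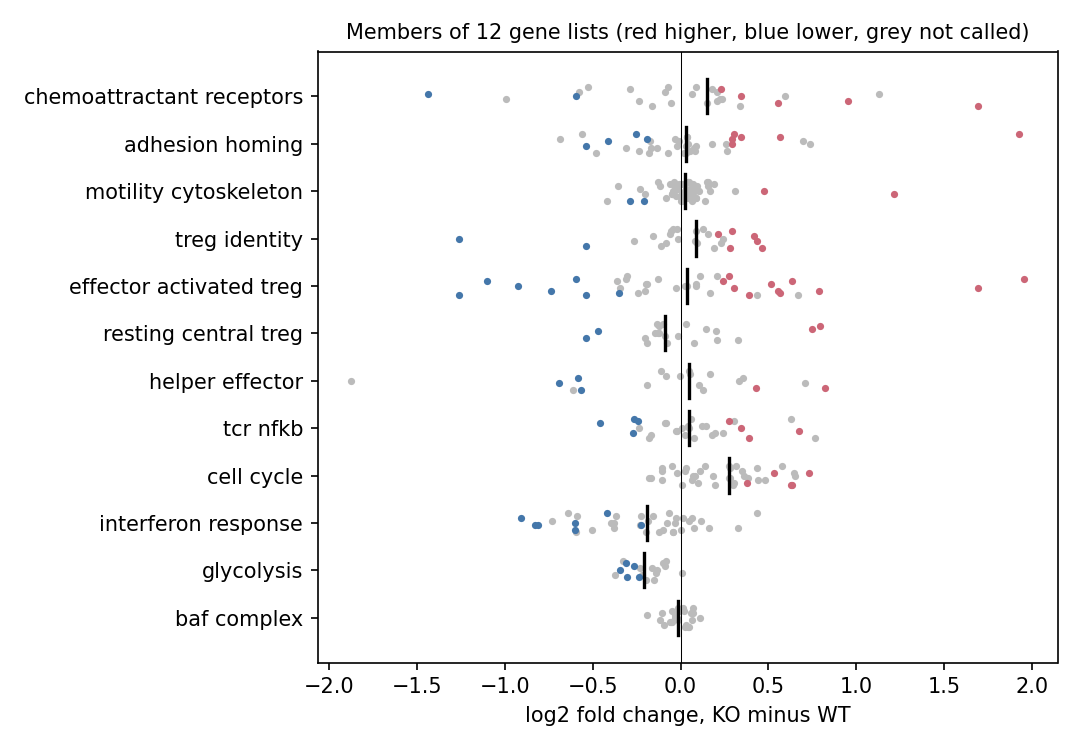
Log2 fold changes (KO minus WT) of the tested members of 12 gene lists, with called members in red (higher) or blue (lower), the others in grey and the list median as a black bar. Members of the receptor, adhesion and effector lists lie on both sides of 0, while the glycolysis median is -0.21 and the cell cycle median 0.28.

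Markers of other cells and signs of handling were measured beside these groups. Markers of gamma delta and innate T cells were lower in KO (camera adjusted p = 0.0250, and adjusted p = 0.603 with an estimated correlation), with 2 of 5 called, among them Tcrg-C1 (log2 fold change -0.57). The list holds genes that other T cells express too. The call of Tcrg-C1 was lost when any 1 of the WT libraries, KO replicate 1 or KO replicate 3 was left out (highest adjusted p = 0.117), and the list fell short without WT replicate 3, KO replicate 1 or KO replicate 2 (adjusted p between 0.0749 and 0.0784). Summed over the listed genes, they had 40.0 ± 0.91 CPM in WT and 29.1 ± 1.53 CPM in KO. The camera adjusted p was 0.0952 for plasma cells, 0.620 for B cells, 0.980 for CD8 T cells, 0.852 for NK cells, 0.608 for macrophages and monocytes, 0.584 for dendritic cells and 0.980 for erythroid cells. Without KO replicate 3 the plasma cell and macrophage lists passed as higher in KO (adjusted p = 2.95e-12 and 4.23e-07), and the plasma cell list passed also without WT replicate 2 (adjusted p = 0.0194). With another library left out their adjusted p-values were up to 0.316 and 0.789, and the macrophage list turned lower without KO replicate 2 (adjusted p = 0.252). With all libraries and an estimated correlation the 2 lists had adjusted p = 0.897 and 0.950. With the male share as a covariate both passed as higher (adjusted p = 0.00477 for plasma cells and 0.00857 for macrophages). Of 18 macrophage and monocyte markers and 5 erythroid markers, 0 were called by edgeR, DESeq2 or limma-voom, and 1 and 0 had an unadjusted p under 0.05. Summed macrophage and monocyte markers had 498.9 ± 16.3 CPM in WT and 563.7 ± 163.4 CPM in KO, with 527.1, 742.2 and 421.7 CPM in KO 1, 2 and 3. Dendritic cell markers summed to 178.0 ± 37.6 CPM in WT and 115.0 ± 17.7 CPM in KO, and to 87.6 ± 13.2 and 81.4 ± 8.55 CPM without the chemoattractant receptors on that list, Ccr9 among them. The sums were 187.6 ± 4.70 and 197.6 ± 26.3 CPM for plasma cells, 39.7 ± 1.42 and 38.2 ± 0.56 CPM for CD8 T cells, 11.4 ± 0.76 and 12.7 ± 3.61 CPM for NK cells, and 86.8 ± 2.01 and 91.2 ± 3.73 CPM for erythroid cells, in WT and KO. Neutrophil and platelet markers had 2 tested genes each and were not tested as lists: their summed levels were 10.7 and 4.04 CPM in WT and 7.29 and 4.43 CPM in KO. B cell markers summed to 1595 ± 155 CPM in WT and 1532 ± 130 CPM in KO. Among B cell markers Cd79b had a log2 fold change of -0.69 and Cd22 of 1.19. Among the others Sdc1 had one of 2.84, from a WT level near the floor (0.18 CPM in WT, 1.39 in KO). Prf1 had one of -0.68, Klrb1c of -1.14 (2.58 and 1.17 CPM in WT and KO) and H2-DMb2 of -1.72 (2.51 and 0.76 CPM). All but H2-DMb2 lost their calls without WT replicate 1 (highest adjusted p with a library left out 0.146, that of Klrb1c). The calls of Cd22, Prf1, Sdc1 and Klrb1c were lost also without WT replicate 2, those of Prf1, Sdc1 and Klrb1c without WT replicate 3, and that of Klrb1c without KO replicate 2 or KO replicate 3 and with the male share as a covariate (adjusted p = 0.0630). Hba-a1 (adjusted p = 0.261) and Ly6c2 (adjusted p = 0.175) did not pass, but Hba-a1 did with the male share as a covariate (adjusted p = 0.0136) and without KO replicate 3 (adjusted p = 0.0460, and up to 0.854 with another library left out), and Ly6c2 without KO replicate 1 (adjusted p = 0.0342, and up to 0.418). Of the 25 stress and dissociation genes 1 rose and 2 fell (4 adjusted over the list alone, camera adjusted p = 0.669): Egr1 (-0.38) and Ier2 (-0.31) fell, and Klf4 (0.60) lost its call when any 1 library but WT replicate 3 was left out (highest adjusted p = 0.150) and with the male share as a covariate (adjusted p = 0.0508). The list passed, as higher in KO, without KO replicate 2 (adjusted p = 0.00136, and up to 0.857 with another library left out) and without the libraries lacking Y chromosome transcripts (adjusted p = 0.0275). Mitochondrial transcripts did not pass (0 of 10 called by edgeR, DESeq2 or limma-voom, 0 with an unadjusted p under 0.05, camera adjusted p = 0.584, smallest p that of mt-Co3 with a log2 fold change of 0.17).

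The sex of the mice is not given in the labels, and the libraries differed in sex-linked transcripts within both genotypes. Y chromosome transcripts (Ddx3y, Eif2s3y, Kdm5d and Uty) had 0 reads in WT 1 and KO 2, 3011 and 4879 reads in WT 2 and WT 3, and 6064 and 10132 reads in KO 1 and KO 3. Xist, expressed from the inactive X chromosome, had 8266, 5339 and 2569 reads in WT 1, 2 and 3, and 1763, 8541 and 0 reads in KO 1, 2 and 3. Of the 6 libraries, 3 held both Xist and Y chromosome transcripts. Of the 5 sex-linked genes tested, 0 passed in edgeR, DESeq2 or limma-voom and 0 had an unadjusted p under 0.05 (camera adjusted p = 0.980, smallest p that of Uty with a log2 fold change of 1.03). The spread within each genotype is so wide that this does not show balance. The male share, Y chromosome CPM as a percent of KO 3, was 0, 31.8 and 53.8% in WT 1, 2 and 3. In KO 1, 2 and 3 it was 66.9, 0 and 100%. By camera the list passed as lower in KO with this share as a covariate (adjusted p = 0.0394). It passed as higher without the libraries lacking Y chromosome transcripts (adjusted p = 0.00111). Genes of this list make up the male share, and the libraries were left out by the same genes. Neither result can therefore tell of a difference between the genotypes.

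**Figure D5:**
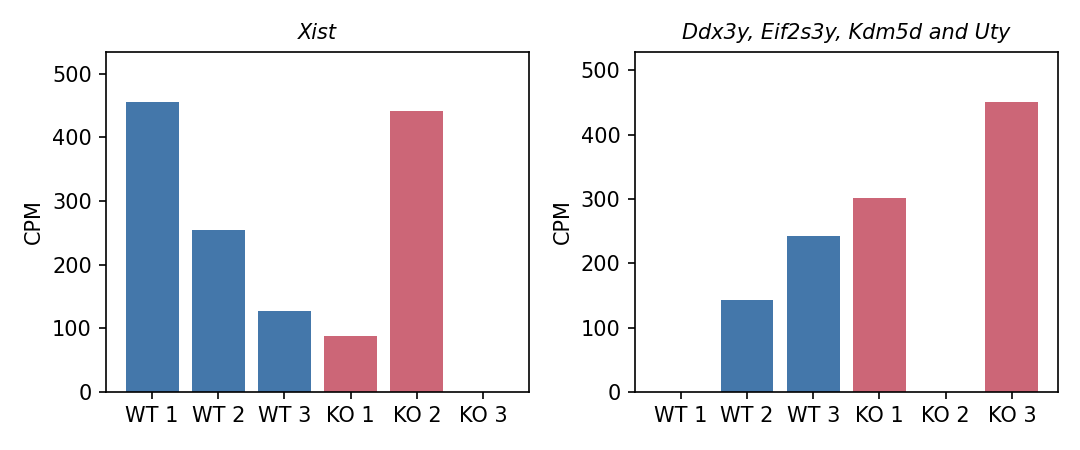
CPM of Xist (left) and summed CPM of 4 Y chromosome genes (right) in each library, WT in blue and KO in red. WT 1 and KO 2 have no Y chromosome reads, KO 3 has no Xist reads, and the other 3 libraries have both.

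A conventional knockout can carry a flanking segment from the strain in which the allele was made, so genes near Smarcd2 were counted. Within 10 Mb of it, 17 of 261 tested genes were called (6.51%), against 6.45% of tested genes elsewhere (Fisher's exact test, 2-sided, p = 0.899). Among the 17 is Cd79b (106311341 to 106314762), 38.4 kb from Smarcd2. Cntnap1, Ccr10 and Top2a, named above, are among them too, 5072, 5088 and 7239 kb away. On chromosome 11 as a whole 68 of 1099 tested genes were called (Fisher's exact test, p = 0.749).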

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

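Fits with the male share, with the GC and length correction and without the libraries lacking Y chromosome transcripts were chosen after seeing the data. Smarcd2 was called in every fit, with log2 fold changes from -1.79 to -1.75 when libraries were left out. The 877 changed genes became 1624 with no filter on low counts, 234 against a fold of 1.2, 201 with a fold of at least 2, 1355 at an adjusted p under 0.1 and 186 without the libraries lacking Y chromosome transcripts, where fewer libraries enter. With 1 library left out they were between 344 and 848, of which 335 to 705 were among the 877. The other settings gave 738 to 990. With the replicate block 738 genes (687 shared) and 6 lists were called, the added list being that of plasma cells (adjusted p = 0.0159). Of the named genes 8 lost their call with this block, with adjusted p-values of 0.124 for Rpl7, 0.0797 for Rgs10, 0.0601 for Dapl1, 0.0586 for Slc16a1, 0.0570 for Rps7, 0.0569 for Ifit2, 0.0567 for Slc2a1 and 0.0531 for Rpl37, and the block changed no other call of a named gene. The numbers share no known litter or day, and same-number deviations correlated at -0.14, -0.05 and 0.15, and WT 1 went best with KO 2 (0.23), so the libraries are not taken as paired. Of 79 called named genes besides Smarcd2, 53 kept their call in the 12 settings run on single genes (RLE, DESeq2, limma-voom, the block, each of the 6 libraries left out, the male share, and the GC and length correction). Without the libraries lacking Y chromosome transcripts, which leaves 2 per genotype, 17 of these 53 lost it, among them Gcnt1, Dsp, Ccr10, Icam1, Itgae, Oas2 and Isg20 (adjusted p from 0.0587 to 0.0924 over the 17). Among the named genes direction turned for Uty (-1.18) and Smarcd1 (0.0277) with the male share. Uty is itself part of the male share, so its value in that fit cannot be read as an effect of genotype. With 1 library left out Smarcd1 lay between -0.0803 and 0.0445 and Smarcd3 between -0.10 and 0.24. For Smarcd1 and Smarcd3 the cause was not tested. Of the 24676 genes with a read 13602 had the depth to be tested, and a 2-fold change was called for 80% of simulated genes.

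The 5 called lists became 0 with an estimated correlation, 2 with fry, 9 with the male share and between 4 and 9 with 1 library left out. With the male share the sex-linked list was among them, and genes of that list make up the share. Direction turned in at least 1 setting for 14 of the 22 other lists. Their adjusted p-values with 1 library left out lay between 0.209 and 0.894 for adhesion, 0.0685 and 0.956 for B cells, 0.565 and 0.955 for SWI/SNF subunits, 0.748 and 0.973 for CD8 T cells, 0.0449 and 0.989 for cholesterol synthesis, 0.266 and 0.931 for dendritic cells, 0.0878 and 0.952 for erythroid cells, 0.565 and 0.989 for helper effector genes, 4.23e-07 and 0.789 for macrophages, 0.123 and 0.828 for mitochondrial transcripts, 0.463 and 0.952 for NK cells, 0.270 and 0.894 for oxidative phosphorylation, 0.394 and 0.839 for sex-linked genes, and 0.00136 and 0.857 for stress genes. With the male share, turned lists had 0.971 (CD8 T cells, mitochondrial transcripts), 0.301 (erythroid), 0.840 (NK) and 0.486 (stress). With the GC and length correction, CD8 T cells and mitochondrial transcripts had 0.953, and with a filter at 2 CPM CD8 T cells had 0.935. Sex-linked genes had 0.999 with fry. Without the libraries lacking Y chromosome transcripts, turned lists had 0.732 (adhesion), 0.0628 (macrophages) and 0.00111 (sex-linked, where genes of the list itself decided which libraries were left out). Near Smarcd2, 23 genes within 20 Mb and 16 within 10 Mb without Smarcd2 were called, both shares below that elsewhere.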

Other observations

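The tests of the male share, of zinc finger genes elsewhere, of read-through and of a strain or allele difference on chromosome 3, and the splits of the libraries, were chosen after the results they bear on were seen. Genes named here were chosen after their values were seen.

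Genes of the p53 signalling pathway, as the deposited table annotates it, were higher in KO by camera over 295 pathways (adjusted p = 0.0297, and adjusted p = 0.982 with an estimated correlation). Of 62 tested members 10 rose, among them Cdkn1a and Cdkn2a, which encode inhibitors of the cell cycle, and 1 fell. The ribosome pathway was lower (median log2 fold change -0.12 over 127 genes, adjusted p = 0.000143, and adjusted p = 0.982 with an estimated correlation).

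The 6 libraries can be split into 3 and 3 in 10 ways, too few to give a share under 0.05: the real split called 877 genes and the highest other 0, so 1 of the 10 called as many. For gene lists 8 of the 10 splits called at least the 5 of the real split and the highest other called 13, by camera with the preset correlation, where 0 lists of the real split passed with an estimated one. Mixed Xist and Y chromosome transcripts may come from pooled mice of both sexes, but with the male share as a covariate 88.4% of the 877 genes were still called. After the correction for GC content and exon length 92.7% were, which argues against that bias for most of them. An effect of the knockout on these genes stays open beside differences between litters or days, which the labels do not give.

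On chromosome 17, between 21008903 and 22867134, all 20 tested zinc finger genes had higher means in KO (median log2 fold change 0.32), and 17 were higher in every KO library than in every WT library. Counting both directions, chance gives no overlap for 10% of genes, and 25.7% of all tested genes had none. The 5 called genes include Zfp53 (77.0 ± 5.60 to 114.3 ± 1.41 CPM, log2 fold change 0.57, adjusted p = 0.00053) and Zfp52 (0.66, adjusted p = 0.000823). Zfp820, given above among the largest rises, is another of them. After the GC and length correction the median was 77.6% of that before (95% bootstrap interval 69.3 to 90.3) with 3 genes called. This argues against sequence bias as the whole cause. The 306 zinc finger genes elsewhere had a median of 0.0463 (95% bootstrap interval 0.03 to 0.07), a small rise. This argues against a change of the whole family as large as that of the cluster. A strain segment around the cluster cannot be told apart from an effect of the knockout: within 20 Mb 5.76% of other tested genes were called against 6.44% elsewhere (Fisher's exact test, p = 0.684), and such a segment need not alter its neighbours. These genes are close paralogs whose shared reads were not tested, and an effect of BAF60b on the cluster is a hypothesis.

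The processed pseudogene Gm33707 (chromosome 3, 60769887 to 60770455) had 0 reads in each WT library and 132, 145 and 129 reads in KO 1, 2 and 3, at least 129.5-fold higher against a floor of 3 counts over the group. Its neighbour Gm38326 had 0 reads in WT and 10, 6 and 12 in KO (at least 8.93-fold higher by the same floor). Gm33707 lies 140 kb past the end of Mbnl1, a splicing regulator that rose from 1387 ± 10.1 to 2046 ± 117 CPM (log2 fold change 0.56, adjusted p = 0.000414). Read-through in proportion to Mbnl1, at the ratio seen in KO, would have left 262 reads of Gm33707 in WT, where 0 were seen. The lower 95% Poisson limit was 231, which covers counting error only. Read-through that occurs in KO alone was not tested. Mbnl1 is on the plus strand and Gm33707 on the minus strand, so read-through would be counted only if the counting ignored strand. A strain or allele difference carried by the KO mice cannot be told apart from an effect of the knockout, since gene counts carry no variants and 1 of the other 4 tested genes within 1 Mb (Mbnl1) was called; reads of a pseudogene may also come from its parent gene.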
